A study of Mus musculus with 2 samples.

How the data were processed

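MicroRNA sequencing libraries had been made from total RNA of mouse adrenal gland, with inserts below 30 nt per the labels. Both libraries came from C57BL/6J mice, an inbred laboratory strain, and the labels number them as biological replicates 1 and 2 of 1 group. They give the replicates separate biosample records but the same donor record, so the replicates are not shown to come from separate animals, and the spread between them may be technical. Age and developmental stage are given as unknown. A free-text label calls the tissue wild type (WT) and male, while the field for sex says that it was not collected.

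The authors deposited raw counts, in 1 table per library. Genome build mm10 and gene annotation GENCODE M21 are named in the description files that accompany the tables. The labels link a small RNA library protocol and an adapter trimming protocol. The aligner, the counting tool and their versions are not given in the sources used here. Each deposited table holds 4 summary lines of counts and 2202 miRNA genes, with 3 columns of whole-number counts and no header. The columns were taken as counts without regard to strand, counts on the strand of the gene and counts on the opposite strand, because the second column held the larger sum and no ambiguous read, while the third, at genes with no miRNA gene annotated opposite them, held 199 reads in replicate 1 and 50 in replicate 2. Reads that mapped to several places stand in a summary line of their own and enter no gene. The tables count reads per hairpin gene, so the arms of a hairpin are not separated, and a mature miRNA made from identical copies at several loci is undercounted. The unmapped, multimapping, no-feature and ambiguous lines were left out of library sizes and tests.

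Counts on the strand of the gene were used throughout. All 2202 identifiers matched GENCODE M21, which gave symbols, 1-based mm10 positions and host genes on the same strand. Depth-scaled counts (CPM) were computed over the counts assigned to miRNA genes. A miRNA gene was called detected at 10 CPM or more in both replicates. Levels are given as a percent of assigned counts or as CPM, with the mean and the SD over 2 replicates. Libraries were scaled by TMM in edgeR 4.0.16 under R 4.3.3, which gave factors of 0.994 and 1.006. With 1 group, no comparison between groups exists and no gene was tested between conditions.

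The replicates were compared with each other by an exact two-sided binomial test per miRNA gene, with the expected share taken from TMM-scaled library sizes, for genes with at least 10 counts over both replicates and Benjamini-Hochberg adjustment at 0.05. This test compares 2 libraries and measures how far their spread exceeds counting noise. Log2 ratios are replicate 2 over replicate 1 with 0.5 counts added, and their 95% intervals are exact binomial intervals. Intervals cover counting error only, since sequenced copies of 1 molecule cannot be told from separate molecules here. The common dispersion was estimated in edgeR with an intercept-only design and is given as a coefficient of variation, with an interval from 100 bootstraps over genes. Correlations were computed across genes on log2(CPM + 1) for genes with at least 10 counts in at least 1 replicate, and genes are not independent replicates, so they carry no p-value.

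On counts simulated for the real genes, the binomial test on 443 genes called 61% of 100 genes changed 1.5-fold, 90% of 100 genes changed 3-fold and 0.81% of 247 unchanged genes. That simulation held counting noise only and was given the true scaling, so it does not cover errors of scaling. Simulated coefficients of variation of 10%, 30% and 50% were recovered as 9.37%, 31.7% and 49.4%. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 did all other calculations, and matplotlib 3.10.9 drew the figures.

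The groups of miRNAs, the thresholds and tests used in the report and the rule for named genes were fixed before the data were examined. Most tests of the closing part were chosen later, as stated there. The 19 lists hold 194 distinct miRNAs, of which 7 stand in 2 lists, and all were found in the tables, through RefSeq synonyms where names differed. They cover miRNAs of neuroendocrine cells, miRNAs reported to respond to ACTH in adrenal cells, neuronal and glial, endothelial, smooth muscle and fibroblast, erythroid, leukocyte, muscle, liver, kidney and gut, and epithelial miRNAs, the let-7 and mir-30 families, the mir-17~92 clusters, the Hox clusters, the Dlk1-Dio3 and other imprinted regions, the H19X cluster and the testis cluster of the X chromosome. Each list's median log2(CPM + 1) was placed among 10000 random lists of the same size drawn from all 2202 genes, and its median replicate ratio among 10000 random lists matched on mean expression in 10 bins. The text names the 25 miRNA genes with the highest mean CPM, the 4 highest members of each list, and the 5 largest replicate ratios each way among genes with a mean of at least 10 CPM and an adjusted p under the threshold. A few others were chosen after their values were seen and are marked so.

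The alternatives tried were each replicate alone, the column without strand, detection at 1 or 100 CPM or in either replicate, all reads as denominator, a denominator without the most abundant gene, other count filters and pseudocounts, total-count and DESeq2 1.42.0 scaling, and DESeq2 dispersions. Thinning replicate 1 to the total of replicate 2 and ranking without the let-7 family were added after seeing the data. Hairpin genes that share a stretch of 20 nt with a gene at another locus were marked, since reads from that stretch cannot be placed. Genes that overlap each other on opposite strands were not compared in this way. Most lists hold members that share such a stretch, so list shares and numbers of detected members are uncertain.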

Results

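MicroRNA levels were measured in the mouse adrenal gland, the endocrine organ whose cortex makes steroid hormones and whose medulla makes catecholamines. The series holds 1 group with 2 replicates, so the data give the miRNA profile of the tissue and the spread between replicates, and no contrast of conditions. Replicate 1 held 20598186 reads, of which 49.8% (10263894 counts) were assigned to miRNA genes on their own strand. Replicate 2 held 10628898 reads, of which 33.2% (3525666 counts) were assigned. The Wilson 95% intervals of these shares ran from 49.81% to 49.85% and from 33.14% to 33.20%. Unmapped reads made up 13.8% of replicate 1 and 41.4% of replicate 2. Among mapped reads the libraries were closer, with 37.8% and 38.8% multimapping, and 92.9% and 92.6% of uniquely mapped reads were assigned to miRNA genes. Because multimapping reads entered no gene, all levels below refer to reads placed at 1 locus.

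The adrenal profile was led by Mirlet7g, Mir126a, Mir10a, Mir375 and Mir23a, which together took 42.2% ± 0.57 of assigned counts (SD, n = 2). Mirlet7g, of the broadly expressed let-7 family, was the most abundant miRNA gene in both replicates, with 12.4% ± 2.61 of counts. Mir126a, the endothelial miRNA gene within Egfl7, followed with 9.28% ± 0.40. Mir10a, a miRNA gene of the Hoxb region, took 7.86% ± 0.42, and Mir375, known from pancreatic islets and other neuroendocrine cells, took 7.20% ± 0.57. Mir23a took 5.39% ± 0.64. Among these genes, the order of Mirlet7g above Mir126a, Mir10a, Mir375 and Mir23a was the same in both replicates, although replicate 1 gave 14.3% and replicate 2 gave 10.6% for Mirlet7g. In replicate 1, Mirlet7b (49585 CPM) stood just above Mir23a (49348 CPM).

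On mm10, Mirlet7g (ENSMUSG00000065440.1) lies on chromosome 9 from 106178840 to 106178927, in an intron of Wdr82. Mir126a (ENSMUSG00000065540.1) lies on chromosome 2 from 26591357 to 26591429, where the annotation has Egfl7 on the same strand and Mir126b on the opposite strand. Mir10a (ENSMUSG00000065519.1) lies on chromosome 11 from 96317165 to 96317274, outside any annotated host gene. Mir375 (ENSMUSG00000065616.3) lies on chromosome 1 from 74900658 to 74900721 and Mir23a (ENSMUSG00000065611.1) on chromosome 8 from 84208518 to 84208592, both without an annotated host.

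**Figure D1:**
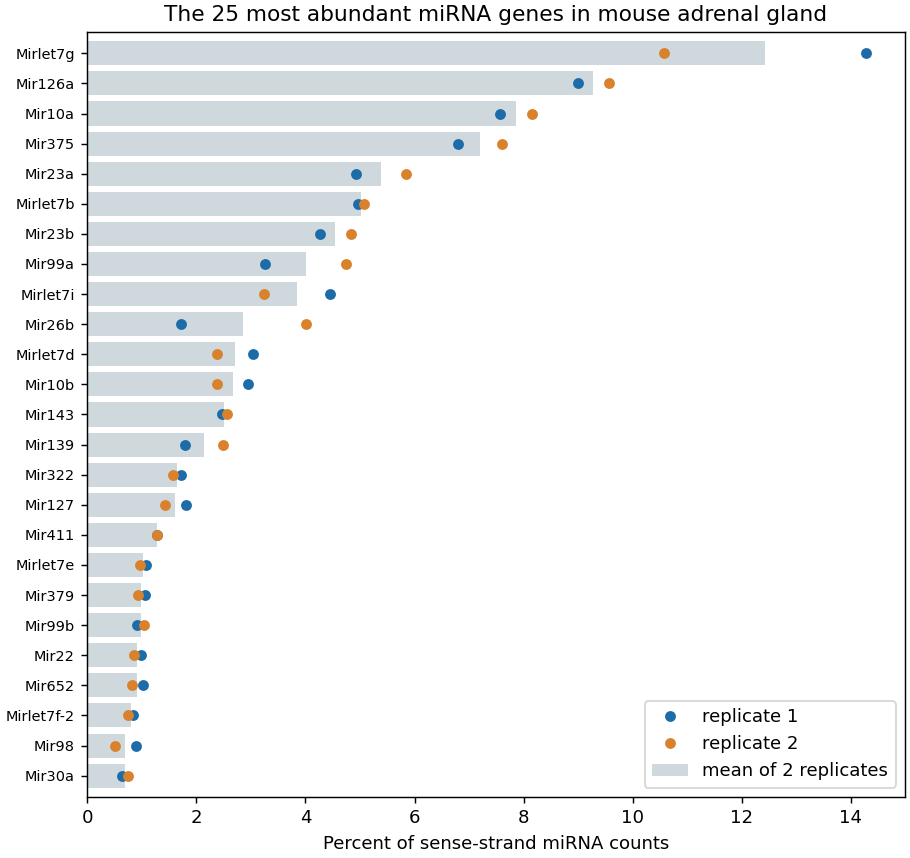
The 25 most abundant miRNA genes, as percent of the counts assigned to miRNA genes on their own strand. Bars give the mean of 2 replicates and points the replicates, and Mirlet7g, at 14.3% and 10.6%, lies above all others in both.

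The next miRNA genes were Mirlet7b at 5.02% ± 0.083 (SD, n = 2), Mir23b at 4.55% ± 0.40 and Mir99a at 4.0% ± 1.06, the last in an intron of the noncoding host gene Mir99ahg. Mirlet7i took 3.85% ± 0.87. Mir26b, in an intron of the phosphatase gene Ctdsp1, took 2.86% ± 1.63, with 1.71% in replicate 1 and 4.02% in replicate 2, the widest relative spread among the 10 leading genes. Mirlet7d (2.72% ± 0.47), Mir10b (2.66% ± 0.40, within Hoxd3 and Hoxd4) and the smooth muscle miRNA gene Mir143 (2.51% ± 0.057) came next. Mir139, in an intron of the cyclic nucleotide phosphodiesterase gene Pde2a, took 2.14% ± 0.49. From rank 15 to rank 25 the mean share ran from 1.64% for Mir322 to 0.690% for Mir30a, and this range held Mir127, Mir411, Mirlet7e, Mir379, Mir99b, Mir22, Mir652, Mirlet7f-2 and Mir98. Mir652 lies in an intron of Tmem164, and Mirlet7f-2 and Mir98 lie in introns of the ubiquitin ligase gene Huwe1, all on the X chromosome. Of these 25 genes, Mir23a, Mir23b, Mir411 and Mirlet7f-2 share a stretch of 20 nt with another hairpin, so their levels are uncertain.

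The profile was concentrated in few genes. The 10 most abundant miRNA genes held 62.4% ± 1.73 of counts (SD, n = 2) and the 25 most abundant 84.0% ± 0.47, and 23 of the 25 were shared between the top ranks of the 2 replicates. In total 267 miRNA genes were detected at 10 CPM or more in both replicates, of which 17 reached 10000 CPM and 60 reached 1000 CPM in both. The miRNA class of the annotation was taken as it stands, and it holds entries with names of other small RNAs. Examples named after their values were seen are Snord43 (170 and 76.6 CPM) and n-TSaga9 (200 and 70 counts). No count was found in either replicate for 1435 of the 2202 genes. Of these, 938 share a stretch of 20 nt with a gene at another locus, so their reads may have been set aside as multimapping and a count of 0 sets no limit on their level. For the others it allows up to 3 counts, or 0.292 CPM in replicate 1 and 0.851 CPM in replicate 2, of uniquely mapped reads. At least 1 count was seen for 730 genes in replicate 1 and 611 in replicate 2, and thinning replicate 1 to the depth of replicate 2 left 621.

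Neuroendocrine miRNAs were abundant. The list of chromaffin, pituitary and islet miRNAs took 7.72% ± 0.48 of counts (SD, n = 2), with 9 of 10 members detected. Mir375 made up most of it. Mir7b followed at 4150 ± 838 CPM, Mir7-1 at 365 ± 161 CPM and Mir7-2 at 205 ± 40.6 CPM. Mir7-1 and Mir7-2 share a stretch of 20 nt and are uncertain.

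The list of miRNAs reported to respond to ACTH, the pituitary hormone that drives adrenal cortical steroid output, took 0.906% ± 0.097 of counts (SD, n = 2), with 10 of 12 members detected. Mir21a led it at 5944 ± 1034 CPM, from within Vmp1. Mir132 had 988 ± 445 CPM, Mir27a 746 ± 100 CPM and Mir214 738 ± 202 CPM. The share of this list is uncertain, since 4 of the 12 share a stretch of 20 nt with a gene at another locus. Among these is Mir466b-1, the sole member without a count. Neuronal and glial miRNAs took 0.217% ± 0.037, with 8 of 18 members detected. The share is uncertain, since 14 of the 18 share a stretch of 20 nt with a gene at another locus, among them all 5 without a count. Mir132, which stands in both lists, led them, followed by Mir137 at 709 ± 161 CPM, Mir338 at 294 ± 52.7 CPM and Mir138-1 at 53.4 ± 28.6 CPM. The levels of Mir27a and Mir138-1 are uncertain, since each shares a stretch of 20 nt with its copy, Mir27b or Mir138-2. No ACTH treatment is part of the series, so these values are levels and show no response.

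MiRNAs of vascular and blood cells were also present. The endothelial list took 9.28% ± 0.40 of counts (SD, n = 2), nearly all of it Mir126a, while Mir126b on the opposite strand had 7 counts and 1 count. In the column without strand, reads at overlapping opposite-strand genes are not assigned, and the endothelial share there was 0.000131%. Smooth muscle and fibroblast miRNAs took 2.69% ± 0.090, with 5 of 7 members detected, led by Mir143, by Mir145a at 980 ± 141 CPM, by Mir214 and by Mir199b at 18.3 ± 9.48 CPM. Leukocyte miRNAs took 0.230% ± 0.003, with 6 of 7 members detected. Their leading members were Mir146 at 841 ± 178 CPM, Mir342 at 629 ± 8.96 CPM, Mir142 at 374 ± 85.1 CPM and Mir150 at 200 ± 90.7 CPM. Mir199b, which shares a stretch of 20 nt with Mir199a-1 and Mir199a-2, and Mir146, which shares one with Mir146b, are uncertain.

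Erythroid miRNAs were the list that differed most between the replicates, with 0.837% of counts in replicate 1 and 0.181% in replicate 2, a ratio of 4.61. Their median log2 ratio lay at the 4.03rd percentile of random lists matched on expression, the lowest of the 19 lists. Among 19 lists, 1 value this low is not unusual. The 4 tested members also differ from separately drawn genes, since Mir144 and Mir451a stand in 1 cluster and Mir486 and Mir3107 overlap. Mir451a, which is abundant in red blood cells, had 8085 CPM in replicate 1 and 1685 CPM in replicate 2. Mir144, from the same cluster, averaged 196 ± 108 CPM (SD, n = 2). Mir486 had 11.5 ± 2.28 CPM and Mir3107, on the opposite strand of Mir486, had 1.06 ± 0.29 CPM. Both levels are uncertain, since genes overlapping on opposite strands were not checked for a shared stretch. The mean of the list, 0.509% ± 0.464, is therefore set by replicate 1, and it was 0.0223% in the column without strand, where reads of Mir451a, which lies opposite Mir451b, are not assigned.

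**Figure D2:**
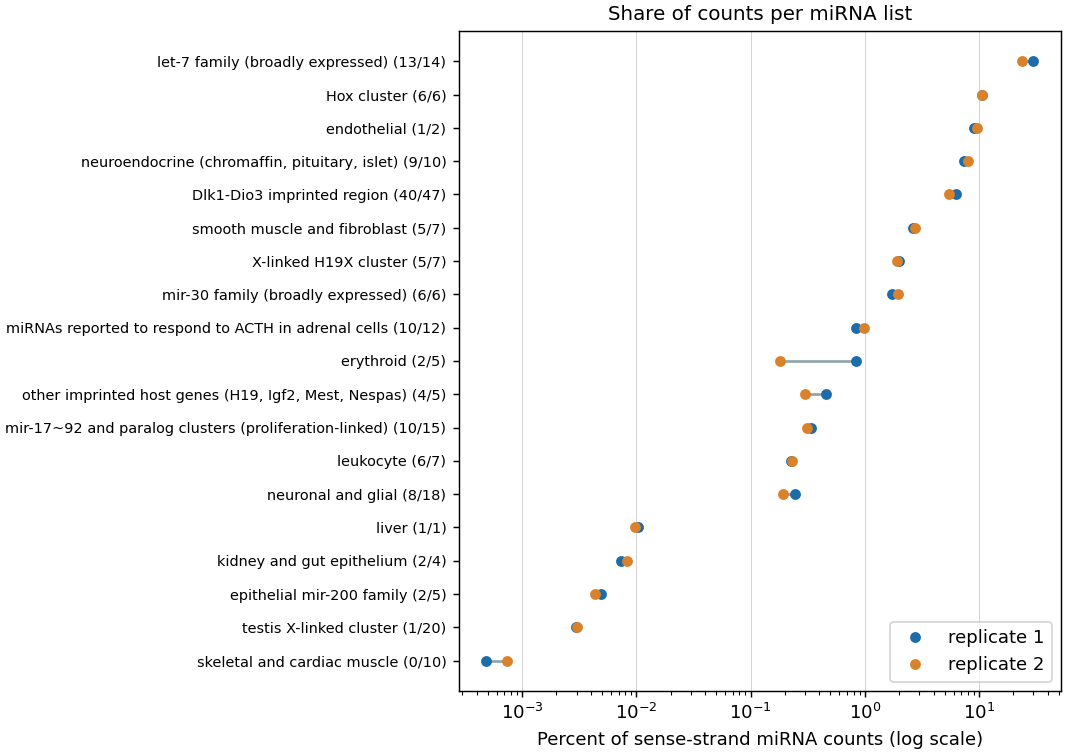
Percent of counts in each of the 19 miRNA lists, on a log scale, with 1 point per replicate and the numbers of detected and measured members in parentheses. The erythroid list, at 0.837% and 0.181%, has the widest gap between replicates.

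The broadly expressed let-7 family held 26.8% ± 4.28 of counts (SD, n = 2), with 13 of 14 members detected and Mirlet7g, Mirlet7b, Mirlet7i and Mirlet7d at its head. Of the 14, 6 share a stretch of 20 nt with a gene at another locus. Their reads may have been set aside as multimapping, so the family share and the order of its members are uncertain. With Mirlet7g taken out of the list and of the total, the remaining members held 16.5%. The mir-30 family took 1.86% ± 0.15, with all 6 members detected, led by Mir30a at 6904 ± 701 CPM, Mir30d at 6899 ± 232 CPM, Mir30e at 4366 ± 664 CPM and Mir30b at 174 ± 7.56 CPM. The mir-17~92 cluster and its paralogs, linked to proliferation, took 0.325% ± 0.020, with 10 of 15 members detected, led by Mir17 at 901 ± 207 CPM and Mir93 at 788 ± 2.80 CPM, then by Mir92-1 at 557 ± 78.1 CPM and Mir106b at 360 ± 38.5 CPM. MiRNA genes of the Hox clusters took 10.6% ± 0.007, and all 6 were detected. This small SD hides opposite changes of its members. Mir10a took 7.56% in replicate 1 and 8.16% in replicate 2, and Mir10b took 2.94% and 2.38%. Mir10a and Mir10b carried most of this share, above Mir615 at 911 ± 176 CPM and Mir196a-2 at 156 ± 19.8 CPM. Mir92-1 and Mir196a-2 are uncertain, since they share a stretch of 20 nt with Mir92-2 and Mir196a-1. The mir-30 share and the order of that family are uncertain too, since Mir30c-1 and Mir30c-2 share one with each other.

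Imprinted miRNA genes were widely detected. The list of miRNA genes of the Dlk1-Dio3 region on chromosome 12, an imprinted domain whose miRNAs are expressed from the maternal allele, took 5.90% ± 0.57 of counts (SD, n = 2), with 40 of 47 members detected. The list does not hold every miRNA gene of the region, and Mir770, Mir673, Mir493, Mir341, Mir1188, Mir3072 and Mir1247, named after their values were seen, were detected outside it. Mir127 led it at 16139 ± 2729 CPM, followed by Mir411 at 12816 ± 37.6 CPM, Mir379 at 9900 ± 867 CPM and Mir382 at 3749 ± 1636 CPM. MiRNA genes of the other imprinted hosts H19, Igf2, Mest and Nespas took 0.381% ± 0.115, with 4 of 5 members detected. Mir335 within Mest led them at 3001 ± 653 CPM, above Mir298 at 537 ± 449 CPM, Mir296 at 263 ± 47.2 CPM and Mir483 within Igf2 at 10.8 ± 0.77 CPM. The H19X cluster on the X chromosome took 1.96% ± 0.047, with 5 of 7 members detected. Its leading members were Mir322 at 16434 ± 1011 CPM, Mir351 at 2766 ± 564 CPM, Mir542 at 207 ± 9.42 CPM and Mir503 at 126 ± 8.31 CPM.

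**Figure D3:**
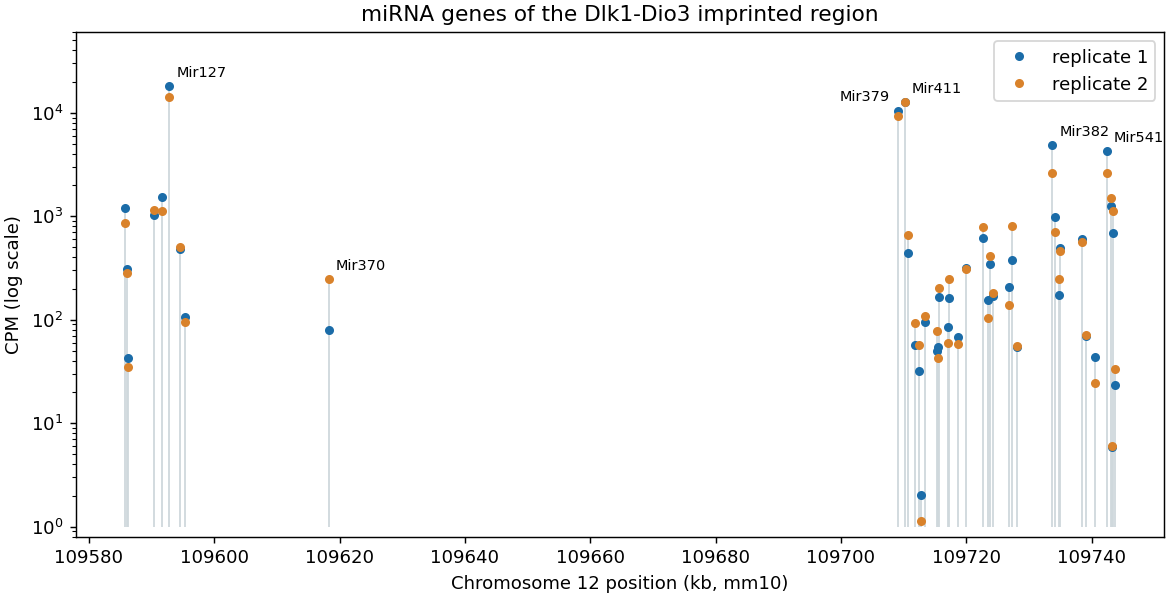
CPM (log scale) of the 42 miRNA genes of the Dlk1-Dio3 list with a mean of at least 1 CPM, against their position on chromosome 12 in kilobases, with 1 point per replicate. Mir127, Mir411 and Mir379 stand highest, and Mir370, between the main clusters, has the largest log2 ratio of the detected members, 1.61.

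Few uniquely mapped reads came from miRNA genes typical of other tissues. Skeletal and cardiac muscle miRNAs took 0.000612% ± 0.000177 of counts (SD, n = 2), and none of the 10 was detected. Of the 6 members without a count, 4 (Mir1a-1, Mir1a-2, Mir133a-1 and Mir133a-2) share a stretch of 20 nt with a gene at another locus, so their level cannot be read from these counts. Among the others, Mir206 had 22 and 9 counts, Mir1b had 13 and 9, Mir499 had 14 and 8, and Mir133b had 1 and 0. The liver miRNA gene Mir122 had 101 ± 4.24 CPM, or 0.0101% ± 0.0004 of counts. Kidney and gut miRNAs took 0.00786% ± 0.00063, with 2 of 4 members detected, namely Mir192 at 58.0 ± 17.0 CPM and Mir194-2 at 18.5 ± 10.1 CPM, above Mir215 with 21 and 6 counts and Mir194-1 with 5 and 0. Mir194-1 and Mir194-2 share a stretch of 20 nt with each other, and Mir133b shares one with Mir133a-1 and Mir133a-2, so these levels are uncertain. The epithelial mir-200 family took 0.00459% ± 0.00039, with 2 of 5 members detected. Mir200b had 14.2 ± 3.16 CPM, Mir429 had 12.1 ± 2.70, Mir200c had 9.94 ± 5.23 and Mir141 had 5.37 ± 0.43. The testis cluster of the X chromosome took 0.00299% ± 0.00002, and 17 of its 20 members, 5 of which share a stretch of 20 nt with a gene at another locus, had no count in either replicate. Mir547 was its sole detected member at 20.3 ± 1.81 CPM, above Mir201 at 9.56 ± 1.49 CPM and Mir743 with 1 and 0 counts. Among random lists drawn from all 2202 genes, the median level lay at the 37.7th percentile for muscle, 44.2nd for testis, 91.3rd for liver, 95.1st for kidney and gut and 98.5th for mir-200 miRNAs, and at 98.3 or higher for each of the other lists. Since 1435 of the genes drawn from had no count, this percentile is near its ceiling for most lists and does not separate lists of high and low level.

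The replicates ranked miRNA genes alike but differed gene by gene. Across 424 genes, Pearson's r of log2(CPM + 1) was 0.986 and Spearman's rho 0.979. By the exact binomial test with Benjamini-Hochberg adjustment, 234 of 443 genes (52.8%) differed beyond counting noise, 94 of them higher in replicate 2 and 140 higher in replicate 1, so the replicates are separate libraries and were counted as 2. Of 277 genes with a mean of at least 10 CPM, 79 lay more than 1.5-fold apart, 35 more than 2-fold and 5 more than 4-fold, and the median gene lay 1.32-fold apart. The biological coefficient of variation was 32.9%, with a bootstrap interval from 29.4% to 35.9%, and the square root of DESeq2's mean dispersion gave 51.1%. The labels do not show whether animals or libraries give rise to this spread.

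The largest ratios below 0 belonged to Mir31, Mir451a, Mir298, Mir34c and Mir107. Mir31 had 345 CPM in replicate 1 and 39.4 CPM in replicate 2, a log2 ratio of -3.14 with a 95% interval from -3.40 to -2.90. The log2 ratio was -2.28 for Mir451a, -1.98 for Mir298, -1.95 for Mir34c and -1.83 for Mir107. In the other direction stood Mir26a-1 with a log2 ratio of 2.78 from 39 and 94 counts, Mir1247 with 2.52, Mir301 with 2.17, Mir26a-2 with 1.79 and Mir195a with 1.78. Mir1247 had 94.6 CPM in replicate 1 and 550 CPM in replicate 2, a 95% interval of the log2 ratio from 2.41 to 2.63. Mir26a-1 and Mir26a-2 share a stretch of 20 nt with each other, and Mir107 shares one with Mir103-1 and Mir103-2, so these ratios are uncertain.

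**Figure D4:**
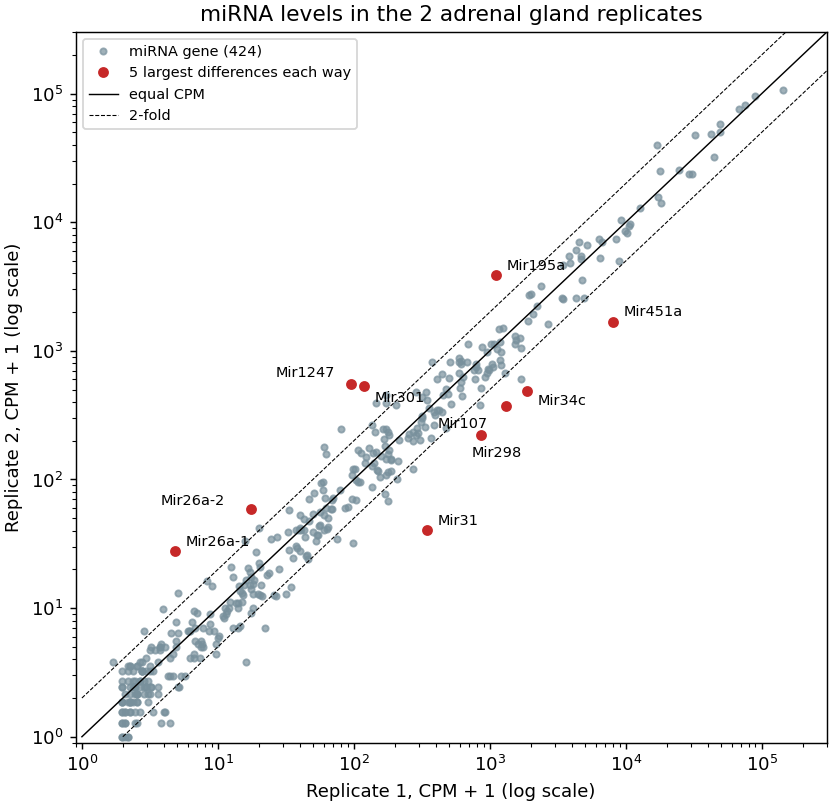
CPM + 1 of 424 miRNA genes in replicate 2 against replicate 1, both on log scales, with a solid line at equal CPM and dashed lines at 2-fold differences. Red points are the 5 largest log2 ratios each way, from Mir31 (-3.14) to Mir26a-1 (2.78).

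In most lists the replicate test called members in both directions. In the Dlk1-Dio3 list, which leaves out some genes of the region, 15 members were higher in replicate 2, 16 were higher in replicate 1 and 11 did not pass the exact binomial test, which makes 31 calls over all genes tested and 32 adjusted over the list alone. In the let-7 family 3 members were higher in replicate 2 and 8 in replicate 1, which makes 11 calls over all genes and 13 adjusted over the list alone. All 10 neuroendocrine members passed, 5 each way, and 10 passed adjusted over the list alone. In the erythroid list 2 of 4 tested members passed, both higher in replicate 1, and 2 passed adjusted over the list alone.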

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

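With 1 group of 2 replicates, no sample was tested as an outlier and no difference between groups existed. The antisense column, which enters no comparison above, was looked at for this part only after the counts had been seen. A miRNA gene was picked where its antisense count was above 3, the limit that a count of 0 allows, in both replicates and no miRNA gene is annotated on the opposite strand. Over all genes with no miRNA gene annotated opposite them, 199 antisense reads were counted in replicate 1, at 51 genes, and 50 in replicate 2, at 26 genes.

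Mir708, on chromosome 7 from 96249424 to 96249532, had 45 antisense reads in replicate 1 and 8 in replicate 2, against 385 and 100 sense counts, and its hairpin shares a stretch of 20 nt with that of Gm23134. Mir203, on chromosome 12 from 112130880 to 112130955, had 16 antisense reads in replicate 1 and 6 in replicate 2, against 5226 and 2873 sense counts.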

How the results depend on the processing

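The thinning of replicate 1 (621 genes with at least 1 count in place of 730) and the ranking without let-7 were chosen after seeing the data. No paired analysis was possible because there is 1 group. With 2 replicates, each alone lies within 1 SD of their mean by construction, so leaving one out tests nothing about shares, and it gave 271 and 282 detected genes. The agreement, the replicate test and the coefficient of variation cannot be had from 1 replicate. Detection at 100 CPM left 167 genes. The 10 leading genes held 66.1% without let-7 and 25.8% of all reads. In the column without strand, 25 genes at 10 CPM or more lose most of their counts, all with a miRNA gene annotated opposite them, and they hold 12.4% of sense counts. Shares there were 0.000131% for endothelial, 0.0223% for erythroid, 1.62% for mir-30, 0.371% for mir-17~92, 2.24% for H19X, 8.79% for neuroendocrine, 3.07% for smooth muscle, 0.220% for leukocyte, 0.0115% for liver, 0.00899% for kidney and gut, 0.00526% for mir-200, 12.1% for Hox and 0.00341% for testis miRNAs. Without Mirlet7g, let-7 held 16.5%, and the smaller total raised the other lists, to 2.12% for mir-30, 0.372% for mir-17~92, 6.75% for Dlk1-Dio3, 2.24% for H19X, 1.03% for ACTH-responsive, 8.81% for neuroendocrine, 10.6% for endothelial, 3.07% for smooth muscle, 0.263% for leukocyte, 0.0115% for liver, 0.00897% for kidney and gut, 0.00525% for mir-200, 12.1% for Hox and 0.00341% for testis miRNAs. Pearson's r was 0.993 with no count filter and 0.978 at 100 counts, and Spearman's rho was 0.880 and 0.970. The replicate test gave 206 to 231 calls under other scalings, no filter and the column without strand. The split between directions moved with the scaling. With DESeq2 factors 102 were higher in replicate 2 and 126 in replicate 1, and with total counts 94 and 137. The coefficient of variation stayed from 32.6% to 33.2% under other scalings and filters, and the square root of DESeq2's mean dispersion, over genes with an estimate above 0, was 51.1% (the cause was not tested).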

Other observations

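Of the tests in this part, the one on GC content was set before its result was seen, and the tests on same-family pairs, neighbouring pairs and blood cell miRNAs were chosen after. The genes named in the next 2 paragraphs were also chosen after their values were seen.

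Many adrenal miRNA genes lay in clusters and host genes. Of the 267 detected miRNA genes, 182 (68.2%) lie in an annotated host gene on their strand, 30 lie on the X chromosome, and 134 (50.2%) lie within 10 kb of another detected gene on the same strand, in 39 clusters. The largest cluster, on chromosome 12 from 109709060 to 109747960, held 32 detected genes and 3.84% ± 0.27 of counts (SD, n = 2). Members of 1 cluster differed widely in level. On chromosome 8, Mir23a had 53905 ± 6444 CPM, Mir27a 746 ± 100 CPM and Mir24-2 289 ± 122 CPM, although all of these share a stretch of 20 nt with the copies on chromosome 13, so reads lost to multimapping limit this comparison.

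Several clustered genes also parted between the replicates. Mir34c had a log2 ratio of -1.95 and its neighbour Mir34b 0.04. Mir195a had 1.78 and Mir497 0.01, Mir298 had -1.98 and Mir296 -0.39, and Mir181a-2 had 1.11 (194 and 145 counts) and Mir181b-2 -1.06 (2119 and 354 counts). The ratios of Mir181a-2 and Mir181b-2 are uncertain, since they share a stretch of 20 nt with Mir181a-1 and Mir181b-1.

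Log2 ratios between the replicates had an SD of 0.70 over 277 genes. A linear effect of GC content of the whole hairpin is argued against as their cause, since removing a linear GC trend lowered this SD by 0.027% (bootstrap 95% interval -0.18 to 1.33). GC content of the sequenced inserts, which are below 30 nt, was not tested. Recovery that follows the miRNA sequence stays open, since the median difference of 105 same-family pairs at distant loci, 0.40, lay inside the middle 95% of relabellings (0.37 to 0.81, 5.07th percentile), and the percentile was 52.0 without let-7. Different cell make-up that moves whole transcription units stays open too, with neighbouring genes at the 14.2nd percentile and at 1.83 without the Dlk1-Dio3 list. Some genes of that region stand outside the list and were kept in the second value. A difference between animals was not tested. A first run counted a percentile over 50 against either explanation, and the bounds of both pair tests were then reset to the middle 95%. The family of Mir7j, a let-7 miRNA, was also corrected, which moved the same-family percentiles from 6.21 and 48.4. Apart from Mir7j, families were read from the number in the gene name. Mir98, which is in the let-7 list, therefore formed no pair, and families whose members carry different numbers were not joined.

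Log2 ratios of the 40 members of the Dlk1-Dio3 list with a mean of at least 10 CPM ran from -0.94 (Mir382) to 1.61 (Mir370), with an SD of 0.55. Mir1247 in Dio3os, which is not in the list, had 2.52.

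Mir451a was lower in replicate 2, with a log2 ratio of -2.28. Fewer red blood cells in replicate 2 may account for it, but Mir144 (-1.20) and Mir486 (-0.41, from 135 and 35 counts) had a median at the 9.60th percentile of matched random lists. These 2 genes are too few to decide. The ratio of Mir486 is also uncertain, since it lies opposite Mir3107 and overlapping genes were not checked for a shared stretch. The 6 leukocyte members did not fall as a set, with a median of 0.20 (SD 0.86). Of these, 3 were called higher in replicate 2 and 2 in replicate 1. That median is 2.48 above Mir451a. However, Mir451a was picked for its extreme ratio, and the median of the 277 genes with a mean of at least 10 CPM was also far above it, at -0.14. The gap therefore cannot decide whether red and white blood cell miRNAs fell alike. Leukocytes that reside in the tissue were not told apart from those in blood.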
